A study of Mus musculus with 8 samples.

How the data were processed

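The deposited data hold one table of read counts per gene and one table of TPM values (transcript abundances scaled to the same total in every library), each with 8 columns, 1 per library. Per the labels, total RNA was taken with Trizol and polyadenylated RNA was sequenced with a standard Illumina protocol. The submitters' notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.4a and featureCounts 2.0.0, and the builds mm10 and GRCm38. Cell Ranger is named there without a version or a role. The annotation release, the strand setting, single or paired ends and the treatment of reads that map to more than 1 place are not given in the sources used here. The count values are whole numbers that the authors left without normalization. The TPM values made by the authors equal the deposited count divided by a fixed length per gene and scaled to the same total in every library, since the implied lengths varied by at most 4.8e-07 (log2) between libraries.

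Columns were matched to samples by the names of the groups. The names of 6 columns match the genotype or treatment labels of mESC, 2C::GFP+/SGC and 2C::GFP+/SA. The other 2 columns are named after a serum replacement (KOSR), match no label, and were given to untreated 2C::GFP+ by elimination. Expression was not used for this assignment, and every comparison with 2C::GFP+ rests on it. All 8 columns were used (0 left out). The design text also names totipotent-like stem cells, which are not analysed here.

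The table holds 55573 genes, of which 19516 have no count in any library. Of the identifiers, 55480 are in GENCODE M21 (GRCm38), which gave the coordinates and symbols, and 93 are not. The filterByExpr function of edgeR kept 20608 genes for testing. Counts were scaled by TMM, whose factors lay between 0.942 and 1.059, and a model with 1 term per group was fitted to all 8 libraries with the robust quasi-likelihood method of edgeR (4 residual degrees of freedom). Quasi-likelihood F tests gave two-sided p-values, adjusted by the Benjamini-Hochberg method over all tested genes in each of 5 comparisons, and genes with an adjusted p under 0.05 were called changed. Fold changes and their standard errors (SE) are on the log2 scale. Each SE was derived as the absolute log2 fold change divided by the square root of the F statistic. The robust method gives genes different degrees of freedom, so genes with the same ratio of value to SE can differ in p. Levels are CPM (counts scaled to a common library total) after TMM, given as mean ± SD with n = 2 libraries per group. The common biological coefficient of variation was 20.6%.

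The 24 gene lists were tested with camera of limma on log2 CPM (prior count of 2), with the preset inter-gene correlation of 0.01 and again with an estimated correlation, and adjusted over the 24 lists of each comparison. Camera compares a list with the other genes. In the DESeq2 alternative the lists were tested with cameraPR of limma on the DESeq2 statistic of each gene. Its list results therefore differ from the main ones in the list test as well as in the fit. With an estimated correlation no list call held in any of the 5 comparisons: the smallest adjusted p was 0.121. The lists hold 697 genes, of which 693 matched an identifier and 4 did not (AF067057, H1f8, Ero1a and Rigi); a gene may stand in more than 1 list. They cover 2C-like and zygotic genome activation genes, maternal oocyte genes, naive and general pluripotency genes, formative and primed pluripotency genes, trophoblast genes, primitive endoderm genes, mesendoderm genes, neuroectoderm genes, fibroblast (feeder) genes, germline genes, imprinted genes, and targets and partners of the compounds with other chromatin regulators. They also cover p53 target genes, hypoxia and iron-response genes, glycolysis genes, sterol biosynthesis genes, JAK-STAT3 target genes, MEK-ERK target genes, canonical Wnt target genes, integrated stress response genes, interferon response genes, proliferation genes, mitochondrially encoded genes and cytosolic ribosomal protein genes. The lists, the test, the alternatives and the rule for naming genes were chosen before the data were examined.

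Genes are named by this rule. In each comparison, the 6 largest rises and the 6 largest falls are taken among called genes with both libraries of one group above both of the other and a mean of at least 10 CPM in the higher group, predicted models excluded. From each described list, up to 3 called members in its more frequent direction and 1 in the other are taken by smallest adjusted p, or the 2 with the highest mean CPM where none is called. A further 13 genes are always eligible: Zscan4c, Zscan4d, Zfp352, Tcstv1, Tcstv3, Pou5f1, Nanog, Sox2, Zfp42, Dot1l, Kdm5b, Cdx2 and Gata6. Some genes taken by this rule are not reported here.

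A group without any count for a gene is set to 3 counts over the group, which gives a lower bound for the fold. With 1 to 3 counts in a group, the ratio is given with a 95% counting interval. Intervals and floors cover counting error only. The labels do not say that replicates are separate cultures, so the p-values measure only the spread between these libraries. Members of the Zscan4, Usp17l, Tdpoz and Tcstv families are near-identical, and values of single members are uncertain because reads could fit several of them. Values of genes that overlap another gene on the opposite strand are uncertain too.

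Power was measured by planting changes in simulated counts with the same depths. Each gene was drawn independently with the same spread in every group, and changes were planted only in genes above a minimum level. In the 5 comparisons edgeR called 50% to 67% of 100 genes changed by 2-fold and 86% to 94% of 100 genes changed by 4-fold, and called 15 to 23 of 20383 unchanged genes. A list planted with a log2 shift of 0.6 was called in every comparison, with 0 of the 23 other lists. Because simulated genes were independent, this could not show false list calls from genes that move together. The larger spread between the 2C::GFP+/SA replicates was not simulated either. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.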

Results

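Gene expression was measured by bulk RNA-seq of polyadenylated RNA in 8 libraries of mouse embryonic stem cells (ESCs), 2 from each of 4 groups. The groups were untreated wild-type ESCs (mESC), untreated cells named 2C::GFP+ after a fluorescent reporter of the 2-cell-like state, 2C::GFP+ cells given 2 µM SGC0946 with LIF (2C::GFP+/SGC), and 2C::GFP+ cells given 2 µM SGC0946 and 2 µM AS8351 with IL6 and its soluble receptor in place of LIF (2C::GFP+/SA). SGC0946 inhibits the histone methyltransferase DOT1L, and AS8351 is described as an inhibitor of the histone demethylase KDM5B. The series asks whether small molecules can move ESCs towards a totipotent-like state. The 2 columns used for untreated 2C::GFP+ were assigned by elimination, and the labels do not say whether cells were sorted for the reporter.

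The libraries held 145810034 and 19544870 counts in mESC, 126660609 and 16474223 in 2C::GFP+, 133694657 and 13902619 in 2C::GFP+/SGC, and 96895327 and 12299931 in 2C::GFP+/SA (replicates 1 and 2). Replicate 1 was 7.46 to 9.62 times as deep as replicate 2 in each group. A gene without a count was below 0.0215 to 0.231 CPM, depending on the library (3 counts of the total). The 10 most abundant genes took 4.35% to 5.46% of the counts and mitochondrially encoded genes 1.97% to 2.58%. The first principal component of log2 CPM held 60.7% of the variance and placed mESC at -166.89 and -189.96, 2C::GFP+ at -5.77 and -4.89, 2C::GFP+/SGC at 47.21 and 47.38, and 2C::GFP+/SA at 143.9 and 129.02. Across genes, which are not independent replicates, the log2 CPM of the 2 replicates correlated with a Pearson r between 0.964 in 2C::GFP+/SA and 0.98 in mESC. The 2C::GFP+/SA replicates differed most: a chi-square test of their counts gave 54.4 per degree of freedom, against 20.4 to 25.3 in the other groups.

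**Figure D1:**
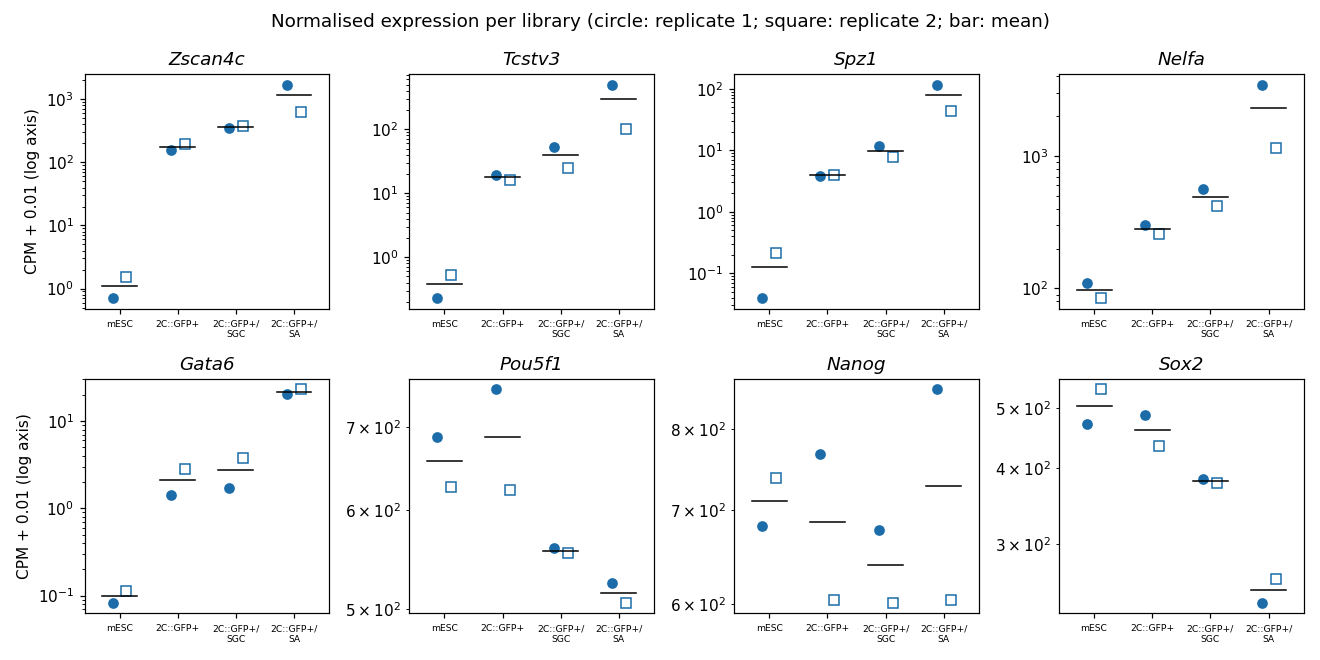
CPM on a log axis of 8 genes in the 4 groups, with a circle for replicate 1, a square for replicate 2 and a bar for the mean. Zscan4c rises from 1.09 CPM in mESC to 176 in 2C::GFP+ and 1170 in 2C::GFP+/SA, with 364 in 2C::GFP+/SGC, where the difference from 2C::GFP+ did not pass the test; Nanog lies between 639 and 728 CPM in all 4 groups.

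The comparison of 2C::GFP+ with mESC asks how the untreated reporter cells differ from ESCs, whose medium the labels do not settle. Genes of the 2-cell-like state and of zygotic genome activation rose the most as a group. If cells were sorted for the reporter, which the labels do not state, such a rise would follow from the selection. Of 54 tested members, 44 rose, 2 fell and 8 did not pass the test (48 higher and 2 lower adjusted over the list alone), and the median log2 fold change was 6.73, or 6.50 with genes without a count in one group set to their bound. The list had a camera adjusted p of 1.33e-29 (adjusted p = 0.245 with an estimated correlation), and its median was 3.49 with limma on log2(TPM + 1) without a filter. Zscan4c (ENSMUSG00000054272, chromosome 7, 11005745 to 11010547), a marker of the 2-cell-like state, averaged 176 ± 28.3 CPM (SD, n = 2) in 2C::GFP+ and 1.09 ± 0.563 in mESC, a log2 fold change of 7.62 ± 0.74 (SE, adjusted p = 0.00212). Duxf3 (ENSMUSG00000075046, chromosome 10, 58229979 to 58232675), whose product DUX switches on genes of the 2-cell embryo, averaged 4.85 ± 0.194 CPM against 0.0219 ± 0.0309 (adjusted p = 5.55e-08). Zfp352 (ENSMUSG00000070902, chromosome 4, 90218820 to 90225702) had 3 counts in mESC, and its ratio was 346 (95% counting interval 118 to 1680). It passed at an adjusted p of 0.00135, and without mESC replicate 1 the adjusted p for Zfp352, 2C::GFP+ vs mESC, was 0.0514. Tcstv1 and Tcstv3 passed at adjusted p = 0.0279 and 0.0362, calls that ended when any library of mESC or 2C::GFP+ was left out (between 0.0694 and 0.224 for Tcstv1, 2C::GFP+ vs mESC, and between 0.11 and 0.238 for Tcstv3, 2C::GFP+ vs mESC). That of Tcstv3 also ended without 2C::GFP+/SGC replicate 2 (0.0595). Among 15 members that share at most 5% of their 31-mers with another gene, 8 rose and 2 fell with a median of 4.67, and among the 39 others 36 rose with a median of 6.93.

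Germ cell genes also rose: 22 of 29 were higher and 1 was lower (26 and 1 adjusted over the list alone), with a median of 2.14 and a camera adjusted p of 2.58e-12 (adjusted p = 0.212 with an estimated correlation). Mael, which acts in the piRNA pathway, rose by 4.09 ± 0.26 (log2, SE) and Stra8, a meiosis gene induced by retinoic acid, by 8.71 ± 0.50. Of 18 maternal oocyte genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone), among them Nlrp14 and Ooep, with a camera adjusted p of 0.00419 (adjusted p = 0.269 with an estimated correlation). Of 19 fibroblast genes, markers of feeder cells, 7 rose and 1 fell (12 and 3 adjusted over the list alone). Their camera adjusted p was 0.0181 (adjusted p = 0.245 with an estimated correlation), and 0.0821 without mESC replicate 1 and 0.0718 without 2C::GFP+ replicate 2. The call also ended with the stricter filter (0.174), limma on log2(TPM + 1) (0.0683) and limma on log2(TPM + 0.1) (0.0604). Gata6 (ENSMUSG00000005836, chromosome 18, 11052064 to 11085635), a regulator of primitive endoderm, rose to 2.13 ± 1.02 CPM from 0.0878 ± 0.0211, while 4 of 26 primitive endoderm genes rose and 3 fell (camera adjusted p 0.0823). That list was called without 2C::GFP+ replicate 1 (0.011) and without the low-count filter (0.012).

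Targets of the MEK-ERK and Wnt pathways moved in opposite directions. Of 18 MEK-ERK targets, 10 rose and 0 fell (11 and 0 adjusted over the list alone; median 1.10, camera adjusted p 4.69e-06, adjusted p = 0.269 with an estimated correlation). The feedback inhibitors Dusp5 and Spry4 rose by 3.37 ± 0.28 and 2.31 ± 0.21, and Myc by 2.13 ± 0.19. Of 18 canonical Wnt targets, 10 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.87, camera adjusted p 5.8e-05, adjusted p = 0.212 with an estimated correlation). Sp5 (ENSMUSG00000075304, chromosome 2, 70474923 to 70477729) went from 91.2 ± 9.43 CPM in mESC to 0.564 ± 0.0424 in 2C::GFP+ (adjusted p = 9.24e-10). Axin2, a feedback inhibitor of the pathway, fell by 2.60 ± 0.19, and Ccnd2, which encodes cyclin D2, rose by 2.31 ± 0.25. The labels name 2 media for ESCs, with and without inhibitors of MEK and GSK3, and do not say which one the mESC libraries came from. Medium and group therefore cannot be told apart in any result of the comparisons with mESC, these pathway targets included.

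The core pluripotency factors did not pass the test between 2C::GFP+ and mESC. Pou5f1 averaged 687 ± 89.7 and 657 ± 43 CPM (log2 fold change 0.06 ± 0.13, adjusted p = 0.77), and the values of Nanog and Sox2 were -0.05 ± 0.17 and -0.13 ± 0.13. Of 34 pluripotency genes, 8 rose and 5 fell (10 and 6 adjusted over the list alone), with a median of 0.08 and a camera adjusted p of 0.321 (0.0421 with limma on log2(TPM + 1) without a filter). Dppa2, a chromatin factor upstream of Dux, rose by 2.96 ± 0.16, and the naive factor Tfcp2l1 fell by 1.95 ± 0.15. Among formative and primed genes 9 rose and 2 fell (11 and 3 adjusted over the list alone), with Dnmt3a up by 2.38 ± 0.19 (camera adjusted p 0.0147, adjusted p = 0.428 with an estimated correlation, and 0.0578 with the stricter filter). Proliferation genes rose in 15 of 30 cases and fell in 1 (15 and 1 adjusted over the list alone; camera adjusted p 0.000459, adjusted p = 0.43 with an estimated correlation). Of 25 sterol biosynthesis genes 9 fell and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p 5.34e-06, adjusted p = 0.245 with an estimated correlation), and of 20 glycolysis genes 8 fell and 2 rose (10 and 2 adjusted over the list alone; 0.000793 and adjusted p = 0.269). The p53 targets fell in 9 of 28 cases and rose in 4 (10 and 4 adjusted over the list alone; camera adjusted p 0.00496, adjusted p = 0.446 with an estimated correlation), and the cell cycle inhibitor Cdkn1a fell by 2.35 ± 0.17.

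In all, 5016 of 20608 genes changed in 2C::GFP+, 3136 higher and 1880 lower, of which 2392 and 945 by at least 2-fold. Under the naming rule the largest rises were in Kdm4dl (2 counts in mESC, ratio 1040, 95% counting interval 287 to 8570), Myo1f, Stra8, Halr1, Ubtfl1 and Wt1, and Myo1f rose by 9.35 ± 0.35. The largest falls under that rule were in Nkx1-2, Sp5, T, Pglyrp1, Trpm1 and Ccbe1, from -8.38 ± 0.56 for the homeobox gene Nkx1-2 to -5.91 ± 0.44 for Ccbe1. Dot1l did not pass (-0.08 ± 0.15), and Kdm5b was higher by 0.53 ± 0.14 (adjusted p = 0.0127). For Kdm5b, 2C::GFP+ vs mESC, the adjusted p was 0.132 without mESC replicate 1, 0.0707 without 2C::GFP+ replicate 1 and 0.0739 without 2C::GFP+ replicate 2. The count was 2837 without mESC replicate 1, 3131 without 2C::GFP+ replicate 1 and 3231 without 2C::GFP+ replicate 2, and limma on log2(TPM + 1) called 2911 genes.

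The comparison of 2C::GFP+/SGC with 2C::GFP+ asks what the DOT1L inhibitor alone does in KnockOut medium with LIF. In the edgeR fit to all 8 libraries no single gene passed, but genes of the 2-cell-like state ranked above the other genes as a group. Many other lists were called as well, as described below. Of 54 members, 52 had a positive log2 fold change, 0 passed over all genes and 5 were higher adjusted over the list alone. Their median was 1.19, and the camera adjusted p was 2.06e-20 (adjusted p = 0.195 with an estimated correlation). Zscan4c averaged 364 ± 10.9 CPM in 2C::GFP+/SGC and 176 ± 28.3 in 2C::GFP+ (log2 fold change 1.05 ± 0.52, adjusted p = 0.575), and the values of Zfp352 and of Nelfa, a regulator of transcription elongation, were 1.69 ± 0.45 and 0.82 ± 0.54. Germline genes had a positive value in 27 of 29 cases with a median of 0.85, and 17 were higher and 1 lower adjusted over the list alone. Their camera adjusted p was 1.73e-12 (adjusted p = 0.159 with an estimated correlation), and Tex19.1, which restrains transposable elements in germ cells, had a log2 fold change of 0.78 ± 0.17 (adjusted p = 0.167). Without 2C::GFP+/SA replicate 1 or replicate 2 the adjusted p was 0.00261 and 0.000888 for Zfp352, 2C::GFP+/SGC vs 2C::GFP+, 0.0297 and 0.0188 for Nelfa, 2C::GFP+/SGC vs 2C::GFP+, and 0.0357 and 0.0443 for Tex19.1, 2C::GFP+/SGC vs 2C::GFP+.

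Pluripotency genes ranked below the other genes, with a median of -0.26, 1 higher and 1 lower adjusted over the list alone, and a camera adjusted p of 6.9e-06 (adjusted p = 0.175 with an estimated correlation). With limma on log2(TPM + 1) their median was -0.143, and without 2C::GFP+ replicate 1 it was -0.164. The log2 fold changes of Pou5f1, Sox2, Nanog and Zfp42 were -0.30 ± 0.13, -0.28 ± 0.13, -0.10 ± 0.17 and -0.43 ± 0.18, and none passed. Ribosomal protein genes had a median of -0.18 (camera adjusted p 3.7e-07, adjusted p = 0.518 with an estimated correlation) and sterol biosynthesis genes of -0.20 (2.51e-05, adjusted p = 0.195 with an estimated correlation). Fibroblast genes had a median of 0.74 (camera adjusted p 9.73e-05, adjusted p = 0.159 with an estimated correlation), and Ccn2, a target of YAP, a value of 0.74 ± 0.16. Integrated stress response genes had a median of 0.34 (camera adjusted p 4.38e-05, adjusted p = 0.195 with an estimated correlation). Also called higher were the neuroectoderm (median 0.615, camera adjusted p 0.00107), mesendoderm (0.622, 0.00679) and imprinted lists (0.099, 0.0464). Called lower were the proliferation (-0.151, 7.36e-05), MEK-ERK (-0.303, 0.00107), JAK-STAT3 (-0.26, 0.0012), glycolysis (-0.122, 0.00174) and mitochondrial lists (-0.175, 0.00679). None of these held with an estimated correlation, and several ended under alternatives. The list of primitive endoderm genes, with a median of 0.42 and a camera adjusted p of 0.046 (adjusted p = 0.518 with an estimated correlation), lost its call under most alternatives, among them DESeq2 (adjusted p 0.0808), limma on log2(TPM + 1) (0.252) and only the 4 libraries compared (0.0659). It also ended without 2C::GFP+/SA replicate 1 (0.0684) or replicate 2 (0.0605), and without 2C::GFP+ replicate 1 (0.962) or 2C::GFP+/SGC replicate 2 (0.986), where the test turned in direction. Dot1l itself had a value of 0.13 ± 0.15 (adjusted p = 0.798).

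With edgeR on all 8 libraries 0 genes changed in 2C::GFP+/SGC, and the smallest adjusted p was 0.116. At an unadjusted p under 0.05 there were 2037 genes, where chance would give 1030. DESeq2 called 271 genes and limma on log2(TPM + 1) called 0. Without 2C::GFP+/SA replicate 1 edgeR called 170 genes and without 2C::GFP+/SA replicate 2 it called 275, and without the low-count filter 499. With only the 4 libraries compared it called 468. Without both 2C::GFP+/SA libraries, an alternative chosen after seeing the data, it called 104.

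The comparison of 2C::GFP+/SA with 2C::GFP+ asks what the full treatment does: SGC0946, AS8351 and the exchange of LIF for IL6 with its soluble receptor. Genes of the 2-cell-like state rose further, from the raised level of 2C::GFP+. Of 54 members, 48 rose, 1 fell and 5 did not pass (53 higher and 1 lower adjusted over the list alone). The median log2 fold change was 3.57, with a camera adjusted p of 1.33e-25 (adjusted p = 0.165 with an estimated correlation). Duxf3 averaged 74.1 ± 3.55 CPM in 2C::GFP+/SA and 4.85 ± 0.194 in 2C::GFP+, a log2 fold change of 3.94 ± 0.24 (adjusted p = 8.38e-07). Tmem92 (ENSMUSG00000075610, chromosome 11, 94777217 to 94782703), a membrane protein gene of the list, rose to 776 ± 266 CPM from 34 ± 0.361 (adjusted p = 9.79e-06), and Arg2, a mitochondrial arginase gene, by 4.11 ± 0.26. Zscan4c rose to 1170 ± 751 CPM (2.73 ± 0.55, adjusted p = 0.0206) and Zfp352 to 133 ± 75.9 (4.48 ± 0.48, adjusted p = 0.00118), while Zscan4d did not pass (2.69 ± 0.70, adjusted p = 0.0504). Without mESC replicate 1, mESC replicate 2 or 2C::GFP+/SA replicate 2 the adjusted p for Zscan4d, 2C::GFP+/SA vs 2C::GFP+, was 0.0386, 0.0415 and 0.0355, and DESeq2 gave 0.00157. The call of Zscan4c ended without 2C::GFP+ replicate 1 (adjusted p 0.127 for Zscan4c, 2C::GFP+/SA vs 2C::GFP+) and without 2C::GFP+ replicate 2 (0.104). So did those of Tcstv1 and Tcstv3 (adjusted p = 0.0316 and 0.0396), at 0.171 and 0.152 for Tcstv1, 2C::GFP+/SA vs 2C::GFP+, and 0.179 and 0.174 for Tcstv3, 2C::GFP+/SA vs 2C::GFP+. Tcstv1 also lost its call without 2C::GFP+/SGC replicate 2 (0.0535), and Tcstv3 without any library of mESC or 2C::GFP+/SGC (0.0523 to 0.0806). Among the 15 members that share little sequence with other genes, 12 rose and 0 fell, with a median of 3.74. The list was higher in 2C::GFP+/SA replicate 1 than in replicate 2, by a median of 1.38 (log2) over its members, and without replicate 1 its median was 2.61.

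Of 26 primitive endoderm genes, 15 rose and 2 fell (18 and 2 adjusted over the list alone), with a median of 2.23 and a camera adjusted p of 5.19e-06 (adjusted p = 0.212 with an estimated correlation). Gata6 went from 2.13 ± 1.02 to 21.7 ± 2.02 CPM (adjusted p = 0.000103), the receptor gene Pdgfra rose by 4.06 ± 0.52, and Hnf4a fell by 1.51 ± 0.32. Of 30 trophoblast genes, 12 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p 0.042, adjusted p = 0.219 with an estimated correlation). The placental gene Peg10 rose by 2.08 ± 0.19, Tead4, a factor of the trophectoderm programme, fell by 2.10 ± 0.21, and Cdx2 did not pass (0.39 ± 0.58). Mesendoderm genes had 5 rises and 1 fall (5 and 1 adjusted over the list alone; camera adjusted p 0.042, adjusted p = 0.185 with an estimated correlation). Neuroectoderm genes had 9 rises and 2 falls (10 and 2 adjusted over the list alone; camera adjusted p 0.0493, adjusted p = 0.539 with an estimated correlation), with Sox1 down by 2.03 ± 0.34. With cameraPR on DESeq2 statistics none of the trophoblast, mesendoderm and neuroectoderm lists was called (adjusted p 0.0764, 0.186 and 0.123). The stricter filter called neither the trophoblast nor the neuroectoderm list (0.356 and 0.509). The trophoblast call also ended without 2C::GFP+ replicate 1 (0.0735) and 2C::GFP+/SA replicate 2 (0.137), and the mesendoderm call without 2C::GFP+ replicate 2 (0.0588) and 2C::GFP+/SA replicate 2 (0.107). The neuroectoderm call ended when either mESC, either 2C::GFP+/SA, 2C::GFP+ replicate 2 or 2C::GFP+/SGC replicate 2 was left out, with adjusted p from 0.0515 to 0.121.

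Fibroblast genes rose in 10 of 19 cases and fell in 0 (12 and 0 adjusted over the list alone), with a median of 1.5 and a camera adjusted p of 0.000363 (adjusted p = 0.165 with an estimated correlation). Ccn2 (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683) rose from 19.7 ± 0.906 to 165 ± 16.3 CPM, and Fbn1, the gene of the matrix protein fibrillin, by 2.14 ± 0.30. Germline genes rose in 17 of 29 cases and fell in 5 (20 and 5 adjusted over the list alone; median 1.40, camera adjusted p 0.000501, adjusted p = 0.218 with an estimated correlation), with Taf7l up by 2.77 ± 0.37 and Stra8 down by 1.83 ± 0.32. Without 2C::GFP+/SA replicate 2 the adjusted p for Stra8, 2C::GFP+/SA vs 2C::GFP+, was 0.0558. Of 37 imprinted genes, 12 rose and 4 fell (12 and 4 adjusted over the list alone; median 0.26, camera adjusted p 0.0125, adjusted p = 0.165 with an estimated correlation). The imprinted RNA H19 rose by 4.49 ± 0.32, Magel2 by 3.99 ± 0.35, and Phlda2 fell by 1.08 ± 0.18. Maternal oocyte genes had 4 rises and 4 falls (5 and 4 adjusted over the list alone), a median of 0.37 with a test in the other direction, and a camera adjusted p of 0.801. Ooep fell by 1.74 ± 0.19. The rise of Oas1e (4.33 ± 1.40, adjusted p = 0.0332) rests on 4 counts in 2C::GFP+ and on 2C::GFP+/SA replicate 1, without which the value for Oas1e, 2C::GFP+/SA vs 2C::GFP+, was -3.88 (adjusted p 0.682). Its call also ended without 2C::GFP+ replicate 1 (0.166), 2C::GFP+ replicate 2 (0.099) and 2C::GFP+/SGC replicate 1 (0.0504).

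Pluripotency genes went both ways: 7 of 34 rose and 13 fell (7 and 15 adjusted over the list alone), with a median of -0.25 and a camera adjusted p of 0.0588 (adjusted p = 0.424 with an estimated correlation). The list was called lower without the low-count filter (0.0118), with only the 4 libraries compared (0.0385), and without mESC replicate 1 (0.041), mESC replicate 2 (0.0384), 2C::GFP+ replicate 2 (0.0232) or 2C::GFP+/SA replicate 1 (0.0367). Sox2 (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461) fell from 461 ± 37 to 252 ± 16.1 CPM (-0.87 ± 0.13, adjusted p = 0.000255), and the naive factors Tfcp2l1, Esrrb and Tcl1 fell by 1.19 ± 0.15, 0.96 ± 0.13 and 1.47 ± 0.19. Nanog did not pass (0.09 ± 0.17, adjusted p = 0.749), and Dppa2 rose by 1.22 ± 0.15. Pou5f1 was lower by 0.42 ± 0.13 (adjusted p = 0.028), and its call ended with DESeq2 (0.0682 for Pou5f1, 2C::GFP+/SA vs 2C::GFP+), without 2C::GFP+ replicate 1 (0.233), 2C::GFP+/SGC replicate 2 (0.0513) or 2C::GFP+/SA replicate 2 (0.0536), and with the stricter filter (0.0628). Formative and primed genes had 6 rises and 3 falls (6 and 5 adjusted over the list alone), among them Nodal, up by 1.46 ± 0.15, and Tead2, down by 1.84 ± 0.13, with a median of 0.02 and a camera adjusted p of 0.766.

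Of 28 p53 targets, 18 rose and 1 fell (19 and 2 adjusted over the list alone), with a median of 0.88 and a camera adjusted p of 7.1e-08 (adjusted p = 0.185 with an estimated correlation). Btg2 (ENSMUSG00000020423, chromosome 1, 134075170 to 134079120), an inhibitor of proliferation, rose from 27.6 ± 2.11 to 132 ± 0.0326 CPM (adjusted p = 1.05e-06), the kinase gene Plk2 rose by 2.57 ± 0.19, and Mdm2, which encodes the ubiquitin ligase of p53, by 1.58 ± 0.15. Proliferation genes fell in 9 of 30 cases and rose in 1 (11 and 2 adjusted over the list alone; median -0.20, camera adjusted p 0.00731, adjusted p = 0.539 with an estimated correlation). The cyclin gene Ccne1 fell by 1.03 ± 0.15 and Ccne2 rose by 1.17 ± 0.19, and DESeq2, the stricter filter and leaving out predicted gene models ended the call of that list (adjusted p 0.0764, 0.246 and 0.069). Of 36 targets and partners of the compounds and chromatin regulators, 9 fell and 0 rose (8 and 0 adjusted over the list alone; median -0.21, camera adjusted p 0.00461, adjusted p = 0.165 with an estimated correlation), and with the stricter filter the median was -0.08 and the call ended (adjusted p 0.223). Chaf1b, a subunit of the CAF-1 histone chaperone, fell by 1.30 ± 0.14 and Ehmt2, a histone methyltransferase gene, by 0.83 ± 0.15. Neither Dot1l nor Kdm5b passed (0.35 ± 0.15 and 0.01 ± 0.14, adjusted p = 0.0957 and 0.96), and for Dot1l, 2C::GFP+/SA vs 2C::GFP+, the adjusted p was 0.0308 without 2C::GFP+/SA replicate 1 and 0.038 with DESeq2.

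Of 20 glycolysis genes, 12 fell and 0 rose (13 and 0 adjusted over the list alone; median -0.65, camera adjusted p 3.91e-07, adjusted p = 0.165 with an estimated correlation), with Aldoa down by 1.32 ± 0.12 and Tpi1 by 1.13 ± 0.13. Of 25 sterol biosynthesis genes, 17 fell and 1 rose (18 and 1 adjusted over the list alone; median -0.64, camera adjusted p 2.86e-07, adjusted p = 0.165 with an estimated correlation), with Sqle down by 1.03 ± 0.12. Of 30 hypoxia and iron-response genes, 12 fell and 4 rose (13 and 4 adjusted over the list alone; median -0.31, camera adjusted p 0.0283, adjusted p = 0.165 with an estimated correlation). Pdk1, which restrains pyruvate dehydrogenase, fell by 1.76 ± 0.13, and the iron exporter gene Slc40a1 rose by 3.08 ± 0.47. The hypoxia list lost its call without 2C::GFP+ replicate 2 (adjusted p 0.106) and without 2C::GFP+/SA replicate 1 (0.109), with the stricter filter (0.139), with limma on log2(TPM + 1) (0.0734) and without predicted gene models (0.0739). Ribosomal protein genes had 8 falls and 1 rise among 60 (2 and 1 adjusted over the list alone; median -0.31, camera adjusted p 0.000363, adjusted p = 0.666 with an estimated correlation). Without 2C::GFP+/SA replicate 2 their median was -0.03, with a test in the other direction (adjusted p 0.974), and the stricter filter ended the call (0.0777).

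Signalling targets moved in different ways. Of 19 JAK-STAT3 targets, 11 fell and 2 rose (11 and 2 adjusted over the list alone; median -0.74, camera adjusted p 0.000827, adjusted p = 0.165 with an estimated correlation). The receptor genes Il6st, shared by LIF and IL6, and Lifr fell by 1.75 ± 0.14 and 1.14 ± 0.17, and Il6ra, the IL6 receptor gene, rose by 3.06 ± 0.37. Canonical Wnt targets had 7 rises and 3 falls (7 and 3 adjusted over the list alone), with Axin2 up by 1.63 ± 0.18 and the Wnt antagonist Dkk1 by 7.64 ± 0.83, and their camera adjusted p was 0.125, or 0.0398 with a median of 0.88 without 2C::GFP+/SA replicate 1. MEK-ERK targets had 3 rises and 2 falls (3 and 3 adjusted over the list alone), a median of -0.21 with a mean of 0.01, and a camera adjusted p of 0.39. Integrated stress response genes had 10 falls and 3 rises, interferon response genes 5 falls and 2 rises (median -0.15, mean 0.34), and mitochondrially encoded genes 0 of either, the same counts as adjusted over the list alone, with camera adjusted p of 0.194, 0.381 and 0.428. The stress response list was called lower without 2C::GFP+ replicate 1 (median -0.43, adjusted p 0.0339), and the mitochondrial list higher without 2C::GFP+/SA replicate 2 (0.29, 0.0432). The interferon list was called lower with the stricter filter (-0.85, 0.0187), limma on log2(TPM + 1) (-0.66, 0.0212) and limma on log2(TPM + 0.1) (-0.81, 0.0194). Psat1, a serine synthesis enzyme gene, fell by 1.22 ± 0.14, Parp14 fell by 1.54 ± 0.24, and mt-Co1 had a value of 0.14 ± 0.14.

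In all, 5910 genes changed in 2C::GFP+/SA against 2C::GFP+, 3072 higher and 2838 lower, of which 2494 and 1088 by at least 2-fold. The share of higher genes, 52%, was 61.7% with upper-quartile factors and 41.8% with limma on log2(TPM + 0.1), so the majority direction turns with the method, and it was 48.4% without 2C::GFP+/SA replicate 1 and 49.9% without 2C::GFP+ replicate 2. Under the naming rule, which asks for a mean of at least 10 CPM, the largest rises were in Olfr815, Tmem72, Calhm3, Olfr881, Drr1 and Olfr1425. They went from 4.83 ± 0.55 for the olfactory receptor gene Olfr815 to 4.61 ± 0.60 for Olfr1425. Without 2C::GFP+ replicate 1 the adjusted p was 0.0888 for Calhm3, 2C::GFP+/SA vs 2C::GFP+, and 0.0768 for Olfr881, 2C::GFP+/SA vs 2C::GFP+, and without 2C::GFP+ replicate 2 it was 0.096 for Calhm3. The largest falls under the naming rule included Ankrd34a, Pou2f3, Jdp2, Slc11a1 and Eno3, from -3.51 ± 0.46 for Ankrd34a to -2.66 ± 0.28 for Eno3. Without 2C::GFP+ replicate 1 the count was 2878, and limma on log2(TPM + 1) without a filter called 3075 genes.

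**Figure D2:**
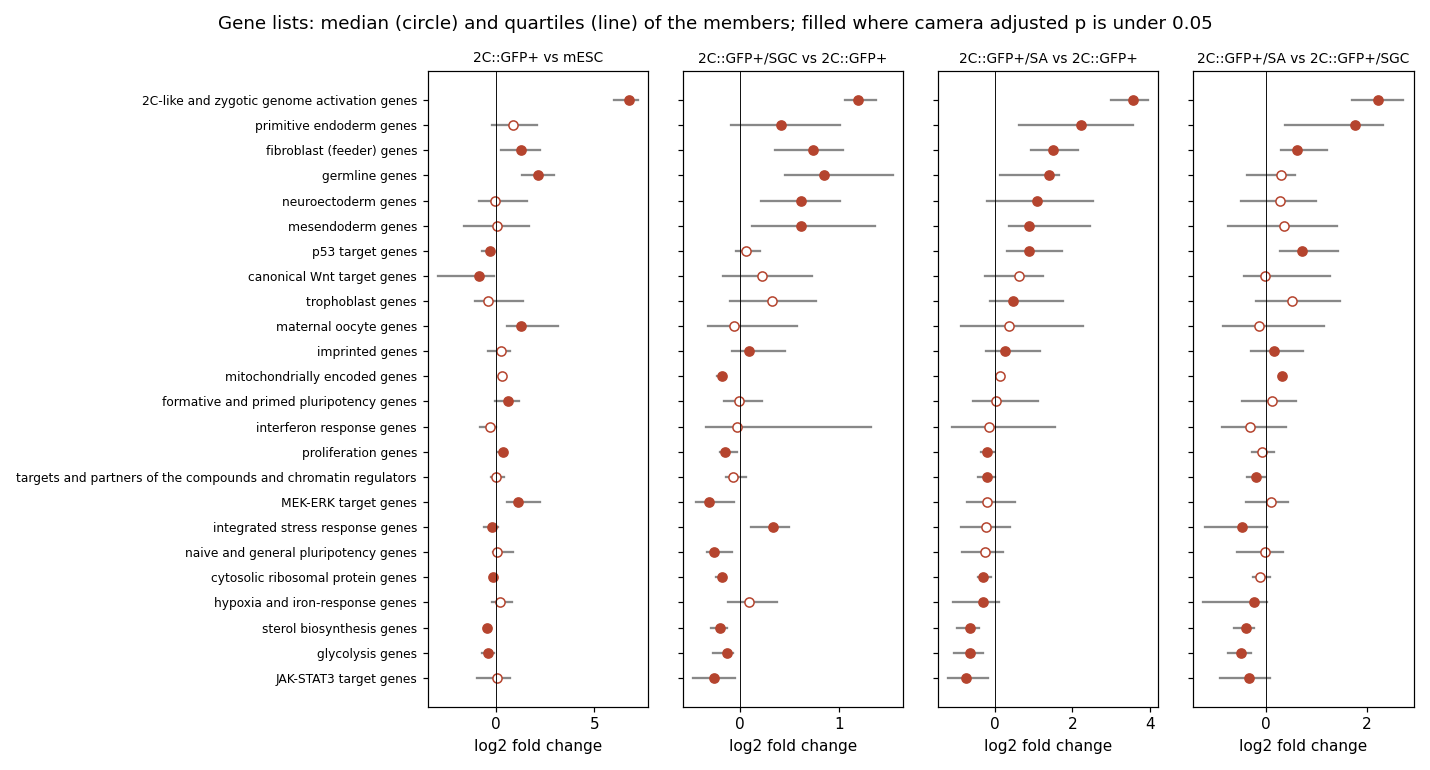
Median log2 fold change (point) and quartiles (line) of the 24 gene lists in 4 comparisons, with filled points where the camera adjusted p with the preset correlation was under 0.05 and a different horizontal scale in each panel. The 2C-like list has the largest median in each panel: 6.73 in 2C::GFP+ against mESC, 1.19 in 2C::GFP+/SGC and 3.57 in 2C::GFP+/SA against 2C::GFP+, and 2.22 in 2C::GFP+/SA against 2C::GFP+/SGC.

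The comparison of 2C::GFP+/SA with 2C::GFP+/SGC asks what AS8351 and the change of cytokine, which differ together, add to the DOT1L inhibitor. Genes of the 2-cell-like state were higher again: 22 of 54 rose and 0 fell (41 and 0 adjusted over the list alone), with a median of 2.22 and a camera adjusted p of 8.8e-22 (adjusted p = 0.195 with an estimated correlation). Without 2C::GFP+/SA replicate 1 the median was 1.36. Duxf3 rose from 11.3 ± 2.93 to 74.1 ± 3.55 CPM (2.73 ± 0.23, adjusted p = 2.24e-05), Arg2 by 2.92 ± 0.24 and Tmem92 by 3.35 ± 0.25. Zscan4c and Tcstv3 did not pass (1.68 ± 0.53 and 2.92 ± 0.90, adjusted p = 0.104 and 0.111). Both passed with DESeq2 and without 2C::GFP+/SA replicate 2, where the adjusted p was 0.000839 for Zscan4c, 2C::GFP+/SA vs 2C::GFP+/SGC, and 0.00674 for Tcstv3, 2C::GFP+/SA vs 2C::GFP+/SGC. Zfp352 rose by 2.80 ± 0.44 (adjusted p = 0.0102), and without 2C::GFP+/SGC replicate 1 or replicate 2 the adjusted p for Zfp352, 2C::GFP+/SA vs 2C::GFP+/SGC, was 0.0583 and 0.0656. Of 26 primitive endoderm genes, 9 rose and 1 fell (16 and 1 adjusted over the list alone; median 1.76, camera adjusted p 6.06e-06, adjusted p = 0.232 with an estimated correlation), with Gata6 up by 3.09 ± 0.42 and Pdgfra by 3.03 ± 0.49. Of 28 p53 targets, 17 rose and 2 fell (18 and 2 adjusted over the list alone; median 0.71, camera adjusted p 4.86e-11, adjusted p = 0.195 with an estimated correlation), with Btg2 up by 1.66 ± 0.14 and Plk2 by 2.10 ± 0.19. Of 19 fibroblast genes, 6 rose and 1 fell, with a median of 0.612. Their camera adjusted p was 0.0115 (adjusted p = 0.195 with an estimated correlation).

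Glycolysis genes fell in 8 of 20 cases and rose in 0 (8 and 0 adjusted over the list alone), with a median of -0.50 and a camera adjusted p of 2.88e-06 (adjusted p = 0.195 with an estimated correlation), and Aldoa fell by 1.24 ± 0.12. Sterol biosynthesis genes fell in 11 of 25 cases and rose in 0 (11 and 1 adjusted over the list alone; median -0.39, camera adjusted p 1.83e-05, adjusted p = 0.195 with an estimated correlation). Integrated stress response genes fell in 9 of 24 cases and rose in 2 (11 and 2 adjusted over the list alone; camera adjusted p 0.00114, adjusted p = 0.245 with an estimated correlation). Psat1 fell by 1.65 ± 0.15, Trib3 by 1.75 ± 0.19 and Chac1 by 2.26 ± 0.36, and Ppp1r15a, a regulatory subunit of the eIF2α phosphatase, rose by 1.11 ± 0.18. JAK-STAT3 targets fell in 8 of 19 cases and rose in 1 (8 and 1 adjusted over the list alone; camera adjusted p 0.0131, adjusted p = 0.195 with an estimated correlation), with Il6st down by 1.49 ± 0.14 and Il6ra up by 2.12 ± 0.35, and the adjusted p was 0.0614 without 2C::GFP+/SA replicate 1 and 0.0533 with limma on log2(TPM + 1). Sox2 fell by 0.60 ± 0.13 (adjusted p = 0.00693), and Pou5f1 and Nanog did not pass (-0.11 ± 0.13 and 0.19 ± 0.17). For Nanog, 2C::GFP+/SA vs 2C::GFP+/SGC, the adjusted p was 0.044 without 2C::GFP+/SA replicate 2. Ribosomal protein genes had 2 rises and 1 fall among 60 (0 and 0 adjusted over the list alone) and a median of -0.13 (camera adjusted p 0.208), which was -0.45 without 2C::GFP+/SA replicate 1 and 0.17 without 2C::GFP+/SA replicate 2, with a call in each case. The list was also called lower with library size only (0.0267), with limma on log2(TPM + 1) (0.00767) and without 2C::GFP+/SGC replicate 1 (0.0294).

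In all, 3319 genes changed between the 2 treated groups, 1633 higher and 1686 lower in 2C::GFP+/SA, of which 1110 and 718 by at least 2-fold. Under the naming rule the largest rises were in Vcam1, Ptprt, Thbs1, Fgfbp1, Mecom and Tmem92, and the cell adhesion gene Vcam1 rose by 3.91 ± 0.40. For Ptprt, 2C::GFP+/SA vs 2C::GFP+/SGC, the adjusted p was 0.0976 without 2C::GFP+/SGC replicate 1 and 0.0552 without 2C::GFP+/SGC replicate 2. For Thbs1, 2C::GFP+/SA vs 2C::GFP+/SGC, it was 0.0502 to 0.132 when any library of mESC, 2C::GFP+ or 2C::GFP+/SA was left out. The largest falls under that rule included Pou2f3, Col5a3, Aurkc, Jdp2 and Stra8, and the meiotic kinase gene Aurkc fell by 2.74 ± 0.33. The count was 1235 without 2C::GFP+/SGC replicate 1 and 1708 without 2C::GFP+/SGC replicate 2. It was 1354 with limma on log2(TPM + 1) without a filter, and the share of higher genes moved from 49.2% to 29.9% with limma on log2(TPM + 0.1) and to 57.5% with DESeq2 size factors.

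The comparison of 2C::GFP+/SA with mESC sets the full treatment against untreated ESCs. Reporter, compounds, cytokine and possibly medium differ together, so their parts cannot be told apart. Here 50 of 54 genes of the 2-cell-like state rose and 2 fell (50 and 2 adjusted over the list alone), with a median of 10.17, or 9.98 with genes without a count set to their bound, and a camera adjusted p of 7.43e-30 (adjusted p = 0.142 with an estimated correlation). Duxf3 rose by 10.87 ± 0.39 and Gata6 by 8.08 ± 0.59. Of 29 germline genes, 27 rose and 1 fell (27 and 1 adjusted over the list alone; median 3.20, camera adjusted p 1.06e-11, adjusted p = 0.121 with an estimated correlation), with Tex19.1 up by 3.6 ± 0.18. Of 25 sterol biosynthesis genes, 21 fell and 0 rose (21 and 0 adjusted over the list alone; camera adjusted p 4.88e-10, adjusted p = 0.121 with an estimated correlation), and of 20 glycolysis genes, 15 fell and 0 rose (16 and 0 adjusted over the list alone; 1.13e-07, adjusted p = 0.121 with an estimated correlation). Sox2 fell by 1.00 ± 0.13 and Tfcp2l1 by 3.15 ± 0.16, while Nanog did not pass (0.04 ± 0.17). Several genes had no count in mESC: Apol7b was at least 4330-fold higher in 2C::GFP+/SA, Fam90a1a at least 3040-fold, Ankrd22 at least 2620-fold and Cd163, a scavenger receptor gene of macrophages, at least 1550-fold. In all, 9288 genes changed, 5143 higher and 4145 lower, of which 4180 and 1994 by at least 2-fold, and the share of higher genes, 55.4%, was 45.8% with limma on log2(TPM + 1). The stricter filter left 6044 called genes, and limma on log2(TPM + 1) without a filter 5964.

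Both treated groups were compared with the same 2C::GFP+ libraries. With edgeR on all 8 libraries 0 genes changed the same way in both, since 0 passed in 2C::GFP+/SGC, and DESeq2 called 249. Of the genes higher in 2C::GFP+/SA, 90.8% also lay above 2C::GFP+ in 2C::GFP+/SGC, and of the genes lower, 86.3% lay below. Simulated groups without any change that shared the control libraries gave 64.5% and 64.2% in the mean of 50 draws. They were drawn around the mean of these same control libraries, which largely removes the error of the controls themselves. The simulated values, the correlation included, therefore understate what shared controls alone would give. The log2 fold changes of the 2 comparisons correlated with a Pearson r of 0.707 across genes, which are not independent replicates, against 0.219 in the simulations. The 2 control libraries were not divided between the 2 comparisons, which would leave each comparison without replicate controls. How much of the agreement comes from the shared controls stays open.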

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

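The alternatives without the 2 libraries assigned by elimination, without the 2C::GFP+/SA libraries, and with all libraries thinned to the smallest total, alone or without the 2C::GFP+/SA libraries, were chosen after seeing the data. With the preset correlation the 2C-like list kept its direction and its call under every alternative in each comparison run, each left-out library included, and with an estimated correlation it had no call in any of the 5 (adjusted p 0.142 to 0.245). Its median ranged from 3.49 to 6.98 in 2C::GFP+ vs mESC, 1.08 to 1.31 in 2C::GFP+/SGC vs 2C::GFP+, 2.61 to 4.03 in 2C::GFP+/SA vs 2C::GFP+, 1.36 to 2.73 in 2C::GFP+/SA vs 2C::GFP+/SGC, and 6.99 to 10.81 in 2C::GFP+/SA vs mESC. No setting called a gene in the direction opposite to the reported one (0 genes). In 2C::GFP+/SGC vs 2C::GFP+ this holds by construction, since 0 genes were called in the main fit. For named genes, 6073 results held under the alternatives set beforehand other than those that leave out 1 library, 271 lost and 56 gained a call; for lists the numbers were 1327, 70 and 38. The minimum of 1 on the absolute log2 fold change gives no list results. DESeq2 size factors moved the median of all genes in 2C::GFP+/SA vs mESC to 0.12 and upper-quartile factors to 0.181, against 0.029, and limma on log2(TPM + 0.1) moved it in 2C::GFP+/SA vs 2C::GFP+/SGC to -0.218 against -0.022.

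The count of changed genes in 2C::GFP+/SGC vs 2C::GFP+, 0 as reported, was 11 with library size only, 499 without a low-count filter and 271 with DESeq2. It was 1 with limma on log2(TPM + 0.1), 468 with only the 4 libraries compared and 284 with a replicate block. Without the 2C::GFP+/SA libraries it was 104, and 234 without them after thinning. Genes changed the same way in both treated groups, 0 as reported, numbered 11, 463, 249, 1, 374 and 269 under the first 6 of these. Across genes, which are not independent replicates, the deviations from the group means of libraries with the same number correlated with r from 0.041 to 0.142, under 0.1 in 3 of 6 pairs of groups, so the libraries were not treated as pairs. Replicate 1 is the deeper library in every group, and a batch shared by number stays open. In 2C::GFP+ vs mESC the count was 2911 with limma on log2(TPM + 1), 3169 with log2(TPM + 0.1) and 1620 with log2(TPM + 1) without a filter. That last setting gave 3075 in 2C::GFP+/SA vs 2C::GFP+, 1354 in 2C::GFP+/SA vs 2C::GFP+/SGC and 5964 in 2C::GFP+/SA vs mESC, where the stricter filter, which tests fewer genes, gave 6044. A minimum absolute log2 fold change of 1 removes smaller changes by construction and left 3337 in 2C::GFP+ vs mESC, 3582 in 2C::GFP+/SA vs 2C::GFP+, 1828 in 2C::GFP+/SA vs 2C::GFP+/SGC and 6174 in 2C::GFP+/SA vs mESC. The pluripotency list in 2C::GFP+/SA vs 2C::GFP+ gained a call without a low-count filter (median -0.205), with limma on log2(TPM + 1) without a filter (-0.296), with only the 4 libraries compared (-0.259) and after thinning (-0.204), and in 2C::GFP+ vs mESC with limma on log2(TPM + 1) without a filter (0.078). With the pseudocount of 1 in limma, which shrinks folds of low values by construction, several list medians fell by more than 1.5 times with the call kept. Apart from the stricter filter, the minimum change and the pseudocount, the cause was not tested.

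With single libraries left out, the library left alone in its group is assumed to vary like the other groups. The counts then ranged from 2837 to 5809 in 2C::GFP+ vs mESC, 0 to 275 in 2C::GFP+/SGC vs 2C::GFP+, 2878 to 5865 in 2C::GFP+/SA vs 2C::GFP+, 1235 to 3152 in 2C::GFP+/SA vs 2C::GFP+/SGC, 6542 to 9175 in 2C::GFP+/SA vs mESC, and 0 to 265 for genes changed the same way in both treated groups. The pluripotency list in 2C::GFP+/SA vs 2C::GFP+ ranged from -0.371 (adjusted p 0.0367, without 2C::GFP+/SA replicate 1) to -0.185 (0.123, without 2C::GFP+ replicate 1). The direction of the test reversed in 3 list results. Primitive endoderm genes in 2C::GFP+/SGC vs 2C::GFP+ ranged from 0.078 to 0.809 and reversed without 2C::GFP+/SGC replicate 2 (0.078) and without 2C::GFP+ replicate 1 (0.112). The list median, cytosolic ribosomal protein genes, 2C::GFP+/SA vs 2C::GFP+, ranged from -0.604 to -0.03 and in 2C::GFP+/SA vs 2C::GFP+/SGC from -0.447 to 0.167, and reversed at -0.03 and 0.167, without 2C::GFP+/SA replicate 2. Oas1e, 2C::GFP+/SA vs 2C::GFP+, ranged from -3.881 (reversed, without 2C::GFP+/SA replicate 1) to 8.174, at 4 counts in 2C::GFP+. The cause was not tested.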

Other observations

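The tests on replicate 1 of 2C::GFP+/SA, on the cytokine, on the spread taken from the 2C::GFP+/SA libraries and on equal depth were chosen only after the result was seen. In 2C::GFP+/SA vs mESC, groups not described above for that comparison also changed. Of 26 primitive endoderm genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone; median 3.54, camera adjusted p 3.49e-05, adjusted p = 0.351 with an estimated correlation). Fibroblast genes rose in 13 of 19 cases and fell in 0 (15 and 0 adjusted over the list alone; camera adjusted p 6.76e-05, adjusted p = 0.121 with an estimated correlation), with Ccn2 up by 4.52 ± 0.18. Imprinted genes rose in 20 of 37 cases and fell in 7 (21 and 7 adjusted over the list alone; camera adjusted p 0.00759, adjusted p = 0.121 with an estimated correlation), with H19 up by 7.35 ± 0.39 and Cdkn1c, a cell cycle inhibitor gene, by 3.15 ± 0.23. Ribosomal protein genes fell in 30 of 60 cases and rose in 1 (32 and 1 adjusted over the list alone; median -0.47, camera adjusted p 1.02e-06, adjusted p = 0.526 with an estimated correlation). Cdx2, a trophectoderm factor, was lower than in mESC by 3.91, and Pou3f1, a factor of the formative state, was higher by 5.44 ± 0.34.

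Of the 13 mitochondrially encoded genes, 7 were counted at means of 457 to 9870 CPM and 6 stayed near 0, at most 0.00258 CPM in the mean: mt-Atp6, mt-Atp8, mt-Co2, mt-Co3, mt-Nd3 and mt-Nd4l. Reads shared with a nuclear copy that were not counted are a candidate explanation. The genes near 0 share a median of 99.2% of their 31-mers with another annotated gene, against 13.5% for those counted. The exception is mt-Atp8, which shares 7.5% and overlaps mt-Atp6. Only annotated transcripts were compared, so a nuclear copy outside the annotation was not tested. Whether the explanation covers mt-Atp8 stays open. Among all annotated genes, 85.8% of 3287 that share over 99% of their 31-mers had no count, against 30.8% of 31041 that share at most 5%. These classes mix all gene types and expression levels, so uncounted reads and silent genes cannot be told apart in them.

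The 2C-like list rose in 2C::GFP+ over mESC and again in 2C::GFP+/SA over 2C::GFP+. Reads shared between near-identical genes could raise many members at once. In 2C::GFP+/SA the 15 members with at most 5% shared 31-mers had a lower quartile of 3.08, against that explanation for those 15. For the 39 others, of which 36 rose and 1 fell, a part for shared reads stays open. The median of 2.61 without 2C::GFP+/SA replicate 1 was against that library as the whole source. In 2C::GFP+ over mESC the lower quartile of those 15 members was 0.24 with a median of 4.67, so shared reads cannot be told apart from a rise of single genes for part of the list. Selection on the reporter, if cells were sorted for it, stays open there too. The cytokine given in place of LIF also stays open for 2C::GFP+/SA, because 0 libraries were given both AS8351 and LIF. SGC0946 was given without AS8351 in 2C::GFP+/SGC (list median 1.19), while AS8351 and the cytokine were not tested apart.

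With edgeR on all 8 libraries 0 genes were called in 2C::GFP+/SGC vs 2C::GFP+ (2037 at an unadjusted p under 0.05, 271 with DESeq2). The spread that the shared model takes from the 2C::GFP+/SA libraries may explain part of this, since without them 104 genes were called. With only the 4 libraries compared, which leaves out mESC too, 468 were called. A replicate block with all 8 libraries kept gave 284. Spread from the mESC libraries and a batch shared by replicate number therefore stay open as well. After thinning all libraries to equal depth (1 draw) 0 genes were called, against the gap in depth between replicates as the whole cause, since the thinned libraries without 2C::GFP+/SA still gave 234 calls. That is more than the 104 at full depth, so the gap may add to the spread, and a part for it stays open together with a small effect of SGC0946. The members of the 2C-like list differed most between the replicates of 2C::GFP+/SA, with 49 of 54 higher in replicate 1.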
